A study of Mus musculus with 12 samples.

How the data were processed

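RNA was measured in 12 flank tumors of C57BL/6 mice with the NanoString nCounter mouse PanCancer Immune Profiling panel, which counts single RNA molecules with bar-coded probes and uses no amplification. Per the labels, the tumors grew from B16F10 cells, a mouse melanoma line, and RNA was taken from formalin-fixed, paraffin-embedded tissue. The panel held 750 probes of genes under study, 20 housekeeping probes, 6 positive controls (spiked-in targets) and 8 negative controls (probes without a target).

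The deposited files of single samples held raw counts per probe, whole numbers with no scaling, per the file headers. The values of the series table were signal that the authors had normalized from the counts before they were deposited, per the labels with nSolver, whose version is not given in the sources used here. Set against the raw counts, each of the authors' values of a gene was the raw count times 1 factor per sample that combined the positive controls and the housekeeping probes, to within 0.00879 percent for counts of 100 or more. All 168 values of control probes in that table equalled the raw counts. Gene names are those of the files; accessions of 746 of 770 gene probes matched a RefSeq gene of the assembly GRCm38.p6, with another symbol for 9, and 24 had no match. No coordinates were used.

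Samples were grouped by their labels into 4 groups of 3. The replicates are separate mice as the labels state. Replicate pairs of a group differed by a chi-square of 24.5 to 156 per degree of freedom, far beyond sampling noise, so each sample was counted once. Total counts of the panel's genes ran from 392596 to 1232726 per sample. A sample's background limit was the mean plus 2 SD of its negative probes; 729 genes lay above it in at least 3 samples and were tested, and 21 were left out.

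The tests were run on the raw counts with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest) in R 4.3.3. All 12 samples entered a single fit of 4 groups, with library sizes proportional to the geometric mean of the 20 housekeeping probes. Every adjusted p is by Benjamini-Hochberg over the 729 genes unless said otherwise, with a threshold of 0.05. There were 6 comparisons of groups, 1 comparison of the second-dose with the first-dose effect, and a joint test of any difference among the 4 groups. Scaled counts are raw counts divided by the relative housekeeping mean. Values with ± are means with SD (n = 3) for counts and log2 fold changes with their standard error (SE) where so named. For a gene below background in every sample of the lower group the fold was computed against the background limits and written as a lower bound, with no fold where that bound lay under 1 or both groups were below background.

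The design, the 30 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with fry from limma 3.58.1, which asks whether a list's genes moved 1 way on balance and does not compare the list with other genes, and with camera with a correlation estimated from the data. Adjustment was over the 29 lists tested; the list of melanocyte and tumor antigens had 2 members on the panel, S100b and Mcam, and was not tested. For each list the count of members past the threshold is given over all genes and adjusted over the list alone.

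The rule named, per comparison, the 8 largest rises and 8 largest falls past the threshold with all samples of a group above all of the other (which chance alone gives for 10% of unchanged genes with 3 against 3 samples) and a mean scaled count of at least 50 in the higher group. For the difference of the effects it named the 6 largest each way. The 3 members of each list with the smallest adjusted p could be named as examples. It also named genes fixed by name, among them Ifng, Cxcl9, Cxcl10, Irf1, Gzmb, Prf1, Cd8a, Cd4, Foxp3, Il2ra, Cd274, Pdcd1, Nos2, Arg1, Il12b, Il2, Il10, Ido1, Ncr1, Ms4a1, Pmel, S100a8 and S100a9; Pmel and S100a9 are not on the panel. Some genes that the rule named are not reported here.

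Alternatives tried were TMM scaling, scaling by the total count of the panel's genes, by the positive controls alone and by the steadier 10 of the housekeeping probes, DESeq2 1.42.0 with its own and with housekeeping size factors, and limma on the authors' normalized values on the scale log2(value + 1). Others were no filter (750 genes), a filter on all samples (562 genes), subtraction of the negative mean, a fit of only the groups compared, the replicate letter as a block, and each of the 12 samples left out in turn. The tests were tried on simulated counts for 729 genes, 200 of them changed. For early single dose against saline edgeR recovered 44% of genes changed 2-fold, 86% at 4-fold and 98% at 8-fold. It called 3 of 529 unchanged genes. For repeat dose against late single dose it recovered 40%, 86% and 96%, and for the difference of the effects 20%, 58% and 94%. The simulated genes varied independently, unlike those of an immune infiltrate, so these rates do not show what would be found in the tumors. Figures were drawn with matplotlib 3.10.9.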

Results

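The data describe how mouse melanomas responded to interleukin-2 and interleukin-12 that had been fused to a collagen-binding protein and injected into the tumor. Interleukin-2 drives the growth of T cells and natural killer (NK) cells, and interleukin-12 drives their production of interferon-gamma. Binding to collagen, the main fiber of the tissue matrix, is meant to hold the cytokines in the tumor. The tumors were B16F10, a poorly immunogenic line of C57BL/6 mouse melanoma cells, grown under the skin of the flank. RNA came from formalin-fixed, paraffin-embedded tissue and was counted with the nCounter system. The panel covered 750 genes of immunity and cancer, of which 729 were above background in enough tumors to be tested.

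The 12 tumors formed 4 groups of 3, each tumor from a separate mouse as the labels state. The design text names 12 mice and 3 per group, but gives 4 for the repeat-dose cohort in 1 place, and 3 were analysed here. Saline tumors and early single-dose tumors were collected 2 days after the first injection, which was given 6 days after the cells were implanted. Late single-dose tumors were collected 8 days after the only dose. Repeat-dose tumors had a further dose 6 days after the first and were collected 2 days after it, which was 8 days after the first. Groups of the same age are saline and early single-dose, and late single-dose and repeat-dose. Saline tumors aged to day 8 are not in the series, so against saline the treatment and age of day-8 tumors cannot be told apart.

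Total counts of the panel's genes were 784379, 737987 and 770752 for saline replicates A, B and C, and 698396, 1232726 and 1028519 for the early single-dose replicates. They were 941352, 612037 and 989732 for the late single-dose replicates, and 1132157, 1038324 and 392596 for the repeat-dose replicates. The geometric mean of the 20 housekeeping probes was 2680 (SD 363, n = 3) in saline and 1716 (SD 410, n = 3) in early single-dose tumors. It was 1467 (SD 221, n = 3) in late single-dose and 919 (SD 341, n = 3) in repeat-dose tumors, by description and without a test. Group means of the total count, in the same order, were 764373 (SD 23845, n = 3), 986547 (SD 269626, n = 3), 847707 (SD 205525, n = 3) and 854359 (SD 402641, n = 3).

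**Figure D1:**
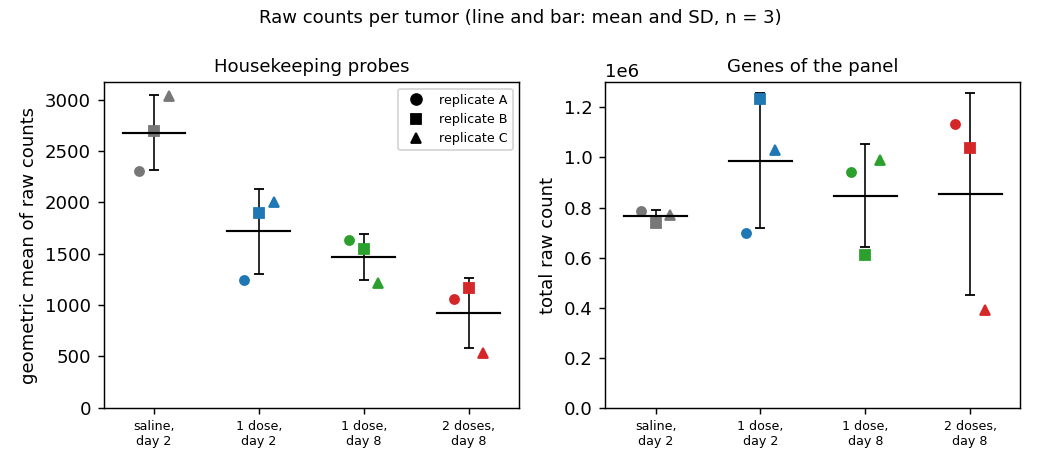
Geometric mean of the 20 housekeeping probes (left) and total raw count of the panel's genes (right) in each of the 12 tumors, by group. Each point is a tumor and each line a group mean (n = 3), for housekeeping probes 2680 in saline and 919 in repeat-dose tumors.

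With counts scaled by the housekeeping probes, the median of all genes moved upward by 0.56 (log2) in early single-dose tumors against saline, 0.78 in late single-dose and 1.195 in repeat-dose tumors. It moved by 0.41 in repeat-dose against late single-dose tumors, 0.08 in late against early single-dose tumors and 0.49 in repeat-dose against early single-dose tumors. Gene values below are log2 fold changes with their standard error (SE), followed by the change relative to that median. Across the 4 groups together, 356 of 729 genes differed in the joint edgeR test at an adjusted p under 0.05. The count was 173 without saline replicate B and 235 without saline replicate C.

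In early single-dose tumors, 2 days after the injection, transcripts of cytotoxic proteins were far above saline. Gzma, a protease of cytotoxic granules, had a mean scaled count of 5339 (SD 1312, n = 3) against 74.4 (SD 66.1, n = 3). Prf1, the pore-forming perforin of the same granules, had 610 (SD 119, n = 3) against 25.1 (SD 9.54, n = 3). Interferon-gamma also rose, with 21 of 25 interferon-gamma response genes, 12 of 16 class I presentation genes and 13 of 20 genes of interleukin-2 and interleukin-12 receptors and signaling, while Kdr, a receptor of blood vessel cells for the growth factor VEGF, fell. The count of T cell markers that rose was 7 of 22, and Cd8a, a marker of cytotoxic T cells, was not among them.

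In edgeR's quasi-likelihood test, 222 genes rose, 5 fell and 502 did not pass. The largest rises were those of Gzma (6.17 ± 0.93 SE, relative 5.61, edgeR adjusted p = 0.00316) and Lcn2, an iron-binding protein of neutrophils (4.64 ± 0.90, relative 4.07, adjusted p = 0.00504). Close behind came Prf1 (4.61 ± 0.53, relative 4.05, edgeR adjusted p = 0.00276) and Gzmb, another granule protease (4.60 ± 0.76, relative 4.04, adjusted p = 0.00316). Marco, a scavenger receptor of macrophages, rose by 4.53 ± 0.96 (relative 3.97, edgeR adjusted p = 0.00761), and Gbp5, an interferon-induced GTPase, by 4.45 ± 0.72 (relative 3.89, adjusted p = 0.00316). H2-T23, a nonclassical class I molecule, rose by 4.29 ± 0.68 (relative 3.73, edgeR adjusted p = 0.00316), and Il2ra, a subunit of the interleukin-2 receptor, by 4.02 ± 0.71 (relative 3.46, adjusted p = 0.00336). Under scaling by TMM, which centers on the bulk of the genes, 143 rose and 54 fell, and under scaling by total count 113 rose and 161 fell. Scaling by the positive controls alone gave 85 higher and 2 lower. Without saline replicate B the count of changed genes was 89, without saline replicate C 107 and without early single-dose replicate B 121.

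The 5 falls were those of Kdr (-1.47 ± 0.21, relative -2.03, edgeR adjusted p = 0.00316) and the integrin Itga4 (-1.36 ± 0.26, relative -1.92, adjusted p = 0.00446), and of 3 further genes. They were the transferrin receptor Tfrc (-0.87 ± 0.20, relative -1.43, edgeR adjusted p = 0.00883), the chromatin protein Hmgb1 (-0.73 ± 0.23, relative -1.29, adjusted p = 0.0374) and the vessel-remodeling factor Angpt2 (-0.62 ± 0.20, relative -1.19, adjusted p = 0.0371). Tfrc had an edgeR adjusted p of 0.0552 without saline replicate B. That of Hmgb1 was 0.102 without saline replicate B, 0.131 without saline C, 0.0943, 0.131 and 0.0651 without early single-dose A, B and C, 0.0577 without late single-dose A and 0.05004 without repeat-dose C. For Angpt2 it was 0.0629, 0.0619 and 0.135 without saline A, B and C, 0.0689, 0.118 and 0.0932 without early single-dose A, B and C, and 0.0545 without late single-dose A. With the positive controls alone Tfrc (adjusted p = 0.0677), Hmgb1 (0.134) and Angpt2 (0.116) did not pass, nor did Hmgb1 with the replicate letter as a block (0.0549) and Angpt2 with the steadier housekeeping probes (0.0592).

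Gene lists were tested with fry and camera. Fry asks whether a list moved to 1 side on balance. Camera compares it with other genes and allows for correlation. Of 29 lists, 15 passed in fry and none passed in camera. Without saline replicate C, 9 passed in fry. Among 25 measured interferon-gamma response genes 21 rose and 4 did not pass (23 rose adjusted over the list alone), with a median 2.46 above that of all genes (fry adjusted p = 0.00751, adjusted p = 0.835 with an estimated correlation). They included the chemokines Cxcl9 (3.56 ± 0.57, relative 3.00, edgeR adjusted p = 0.00316) and Cxcl10 (3.03 ± 0.55, relative 2.47, adjusted p = 0.00389), which attract T cells. The proteasome subunits Psmb8 (3.35 ± 0.52, relative 2.79, edgeR adjusted p = 0.00316) and Psmb9 (3.29 ± 0.53, relative 2.73, adjusted p = 0.00316) were also members. The transcription factors Irf1 (3.02 ± 0.48, relative 2.46, edgeR adjusted p = 0.00316) and Irf8 (3.24 ± 0.54, relative 2.68, adjusted p = 0.00316) rose too. Ifng itself rose by 2.61 ± 0.56 (relative 2.05, edgeR adjusted p = 0.00761). In the type I interferon list 20 of 28 rose and 8 did not pass (20 adjusted over the list alone), with a relative median of 1.32 (fry adjusted p = 0.0115, adjusted p = 0.930 with an estimated correlation). Examples were Zbp1, a nucleic acid sensor (3.84 ± 0.59, relative 3.28, edgeR adjusted p = 0.00316), Ifi35 (2.30 ± 0.37, relative 1.74, adjusted p = 0.00316) and Isg15 (2.61 ± 0.50, relative 2.05, adjusted p = 0.00504).

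Of 10 cytotoxic effector genes 9 rose (9 adjusted over the list alone, relative median 2.18, fry adjusted p = 0.00751, adjusted p = 0.835 with an estimated correlation). Among 20 NK cell markers 11 rose and 9 did not pass (11 alone, relative median 0.521, fry adjusted p = 0.00980, adjusted p = 0.930 with an estimated correlation). Examples were Ncr1, an activating NK receptor (2.23 ± 0.39, relative 1.66, edgeR adjusted p = 0.00336), and Klrg1 (2.26 ± 0.37, relative 1.70, adjusted p = 0.00316). T cell markers counted 7 that rose and 15 that did not pass (7 alone, relative median 0.0260, fry adjusted p = 0.0560). The 7 included Tcf7, a transcription factor of naive and memory T cells (1.19 ± 0.16, relative 0.63, edgeR adjusted p = 0.00316). Tcf7 did not pass with TMM scaling (0.56, adjusted p = 0.111), total-count scaling (0.21, 0.474), the positive controls alone (0.79, 0.264) or DESeq2's own factors (0.52, 0.103). The receptor-signaling genes Cd247 (1.54 ± 0.33, relative 0.98, edgeR adjusted p = 0.00761) and Zap70 (1.43 ± 0.35, relative 0.87, adjusted p = 0.0135) rose too. Zap70 had an edgeR adjusted p of 0.0664 without saline replicate B and 0.0540 without saline C. With total-count scaling the adjusted p of Zap70 was 0.151, and with the positive controls alone 0.167 for Zap70 and 0.123 for Cd247. Cd8a was 0.50 ± 0.38 (relative -0.06, edgeR adjusted p = 0.366) and Cd4, a marker of helper T cells, -0.12 ± 0.43 (relative -0.68, adjusted p = 0.899). Foxp3, the factor that defines regulatory T cells, was 0.62 ± 0.69 (relative 0.06, edgeR adjusted p = 0.569). The regulatory T cell list had 2 of 11 genes that rose (6 alone, relative median 0.333, fry adjusted p = 0.0251, adjusted p = 0.930 with an estimated correlation). Its largest rise was that of Il2ra, which activated T cells and NK cells carry as well. Checkpoint and costimulation genes counted 4 of 16 (2 alone, relative median 0.462, fry adjusted p = 0.0544), among them the inhibitory receptor Pdcd1 (1.25 ± 0.35, relative 0.69, edgeR adjusted p = 0.0240). The edgeR adjusted p of Pdcd1 was 0.0953 without saline replicate B, 0.0922 without saline C and 0.0943 without early single-dose B. Pdcd1 did not pass with TMM scaling (0.67, adjusted p = 0.0834), total-count scaling (0.30, 0.372), the positive controls alone (0.93, 0.222), DESeq2's own factors (0.62, 0.0735) or in a fit of these 6 tumors alone (0.0512).

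The Th1 list had 8 of 13 genes that rose (10 alone, relative median 0.872). The list of interleukin-2 and interleukin-12 receptors and signaling had 13 of 20 (14 alone, relative median 0.829). Both lists had a fry adjusted p = 0.00980 and an adjusted p = 0.930 with an estimated correlation. The receptor subunits Il12rb1 (3.88 ± 0.54, relative 3.32, edgeR adjusted p = 0.00316) and Il2rb (3.30 ± 0.55, relative 2.74, adjusted p = 0.00316) and the signaling inhibitor Socs1 (3.41 ± 0.57, relative 2.85, adjusted p = 0.00316) were among them. The endogenous Il2 gene was at 0.19 ± 0.60 (relative -0.37, edgeR adjusted p = 0.875) and Il12b at -0.53 ± 0.61 (relative -1.10, adjusted p = 0.585). Without early single-dose replicate A the edgeR adjusted p of Il12b was 0.0390, at -1.65. Class I presentation genes rose in 12 of 16 cases (12 alone, relative median 2.18, fry adjusted p = 0.00751, adjusted p = 0.835 with an estimated correlation). The rises included the proteasome subunit Psmb10 (3.17 ± 0.46, relative 2.61, edgeR adjusted p = 0.00316). Class II presentation genes rose in 7 of 10 (8 alone, relative median 2.24, fry adjusted p = 0.00980, adjusted p = 0.930 with an estimated correlation). Members that rose included H2-DMb1 (3.27 ± 0.48, relative 2.71, edgeR adjusted p = 0.00316) and H2-Dma (3.66 ± 0.62, relative 3.10, adjusted p = 0.00322), which load peptides, and their regulator Ciita (3.25 ± 0.60, relative 2.69, adjusted p = 0.00420).

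Inhibitory feedback genes rose in 4 of 13 cases (7 alone, relative median 0.625, fry adjusted p = 0.0140, adjusted p = 0.930 with an estimated correlation). Cd274, which encodes the checkpoint ligand PD-L1, rose by 3.72 ± 0.63 (relative 3.16, edgeR adjusted p = 0.00322). Lymphocyte chemokines had 7 of 15 (7 alone, relative median 0.959, fry adjusted p = 0.0140, adjusted p = 0.930 with an estimated correlation), with the B cell attractant Cxcl13 at 3.06 ± 0.80 (relative 2.50, edgeR adjusted p = 0.0170). For Cxcl13 the edgeR adjusted p was 0.0788 without saline replicate B, 0.0636 without saline C and 0.0797 without early single-dose B. Complement had 10 of 27 (14 alone, relative median 0.862, fry adjusted p = 0.0224, adjusted p = 0.930 with an estimated correlation). These included C4b (3.73 ± 0.63, relative 3.17, edgeR adjusted p = 0.00322) and C1ra (2.91 ± 0.48, relative 2.35, adjusted p = 0.00316). Apoptosis genes had 8 of 18 (10 rose and 1 fell adjusted over the list alone, relative median 0.0668, fry adjusted p = 0.00980, adjusted p = 0.930 with an estimated correlation). Toll-like receptors and adaptors had 9 of 23 (10 alone, fry adjusted p = 0.0494, adjusted p = 0.930 with an estimated correlation), upward in the test although the median of the list lay -0.0238 from that of all genes. The 3 proliferation genes passed downward as a list (0 past singly, 1 fell alone, relative median -0.984, fry adjusted p = 0.0223, adjusted p = 0.7999 with an estimated correlation). Birc5, an inhibitor of cell death made by dividing cells, was at -0.66 ± 0.23 (relative -1.22, edgeR adjusted p = 0.0503), with an adjusted p of 0.0258 without late single-dose replicate B and 0.0102 without late single-dose C. It passed with TMM scaling (-1.30, adjusted p = 0.0291), total-count scaling (-1.65, 0.00803), the stricter filter (0.0405), a fit of these 6 tumors alone (0.0178) and DESeq2 with its own (0.00619) and housekeeping factors (0.0376).

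Lists that did not pass in fry were macrophage markers (6 of 19 rose, fry adjusted p = 0.0504), inflammatory cytokines (5 of 21, 0.0633), alternatively activated macrophage (2 of 14, 0.101), fibroblast and extracellular matrix (2 of 14, 0.106), and dendritic cells (3 of 17, 0.119). Nor did neutrophil markers (3 of 15, fry adjusted p = 0.121), mast cells and eosinophils (3 of 8, 0.173), Th2 (2 of 11, 0.194), epithelium and skin (2 of 6, 0.278), Th17 (1 of 12, 0.455) and B cells (0 of 17, 0.653). Of 17 endothelial genes 2 rose, 2 fell and 13 did not pass (fry adjusted p = 0.953). Fpr2, a receptor of neutrophils and other myeloid cells, rose by 2.01 ± 0.43 (relative 1.45, edgeR adjusted p = 0.00761), and Nos2, which makes nitric oxide in activated macrophages, by 2.72 ± 0.70 (relative 2.15, adjusted p = 0.0160). Without saline replicate B or C the edgeR adjusted p of Nos2 was 0.0780 and 0.0665. Values that did not pass were those of Arg1 (2.13 ± 0.83, edgeR adjusted p = 0.0732), S100a8 (1.54 ± 0.67, adjusted p = 0.101), Ido1 (1.00 ± 0.40, adjusted p = 0.0814) and Il10 (0.89 ± 0.43, adjusted p = 0.138). The B cell gene Ms4a1 (0.13 ± 0.48, edgeR adjusted p = 0.901) did not pass. The edgeR adjusted p of Arg1 was 0.0222 without saline replicate A, and that of S100a8 0.0300 without repeat-dose B. With DESeq2 and housekeeping factors Arg1 (adjusted p = 0.0132), S100a8 (0.0409) and Ido1 (0.0480) passed, as did S100a8 in a fit of these 6 tumors alone (0.0265). Arg1 also passed with the replicate letter as a block (adjusted p = 0.0373), with DESeq2's own factors (0.0316) and with limma (0.0391). On the lower side Cd4 passed with total-count scaling (-1.07, adjusted p = 0.0339) and with DESeq2's own factors (-0.80, 0.0208), where Il12b passed too (-1.27, 0.0455). The list of melanocyte antigens had 2 members on the panel and was not tested.

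**Figure D2:**
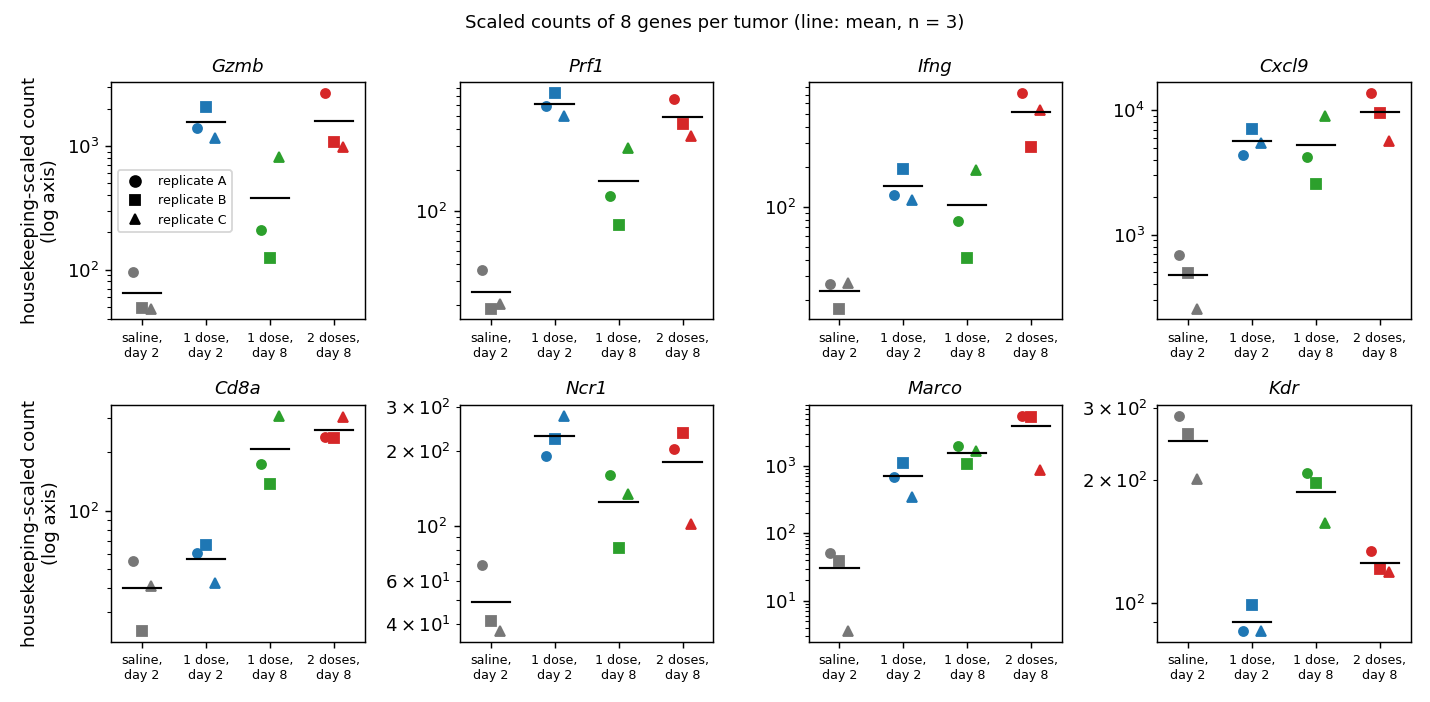
Counts scaled by the housekeeping probes (log axis) of Gzmb, Prf1, Ifng, Cxcl9, Cd8a, Ncr1, Marco and Kdr in each tumor, by group. Each point is a tumor and each line a group mean (n = 3), for Prf1 25.1 in saline, 610 in early single-dose, 166 in late single-dose and 487 in repeat-dose tumors.

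The second dose was read by comparing repeat-dose with late single-dose tumors of the same age. The latter were not injected at the second dose, so here and in the difference of effects cytokines and injection cannot be told apart. Mean scaled counts of Gzmb were 1577 (SD 950, n = 3) after the repeat dose and 380 (SD 372, n = 3) without it. Those of Il2ra were 1067 (SD 569, n = 3) and 154 (SD 106, n = 3), and those of Ifng 513 (SD 219, n = 3) and 103 (SD 77.6, n = 3). Counts of Cd8a were 261 (SD 38.4, n = 3) and 207 (SD 90.7, n = 3). No gene passed the threshold in edgeR, with 77 genes at an unadjusted p under 0.05. DESeq2 called 10 genes with its own size factors and 3 with housekeeping factors (Il2ra, Ifng and Birc5), and limma on the authors' values called 0. With its own factors it called those 3 and, among the named genes, Prf1 (DESeq2 adjusted p = 0.00599), Gzmb (0.0183), Cd7 (0.0302) and Gzma (0.0325).

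The smallest edgeR adjusted p was 0.408, for Il2ra (2.80 ± 0.67, relative 2.39), Ifng (2.32 ± 0.54, relative 1.91) and Birc5 (-1.07 ± 0.23, relative -1.48) among the named genes. Gzma was at 2.51 ± 0.78, Gzmb at 2.06 ± 0.67 and Arg1, an arginine-degrading enzyme of myeloid cells, at 1.77 ± 0.82. Prf1 was at 1.56 ± 0.46 and S100a8, a calcium-binding protein of neutrophils, at 1.48 ± 0.65. Each of these 5 had an edgeR adjusted p of 0.425, as had Socs1 (1.30 ± 0.52), Il12rb1 (1.21 ± 0.48), Cd274 (1.18 ± 0.58), and Nos2 (1.18 ± 0.65). The same held for Irf1 (0.91 ± 0.45), Il10 (0.83 ± 0.43), Pdcd1 (0.68 ± 0.35), Kdr (-0.58 ± 0.21) and Cd7, a T cell surface protein (-0.79 ± 0.37). Further values were Cxcl9 0.87 ± 0.52 (edgeR adjusted p = 0.434) and Ido1 0.61 ± 0.41 (0.482), while Foxp3 was above background in no tumor of either group and has no fold (0.643). For Cxcl10 the value was 0.59 ± 0.51 (edgeR adjusted p = 0.548), for Ncr1 0.55 ± 0.38 (0.486) and for Cd8a 0.34 ± 0.37 (0.612). Those of Ms4a1 (0.15 ± 0.49, edgeR adjusted p = 0.882), Il2 (-0.03 ± 0.63, 0.983), Cd4 (-0.18 ± 0.43, 0.836) and Il12b (-0.36 ± 0.63, 0.774) were smaller than their SE.

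The count of 0 rested on late single-dose replicate C, which lay nearer to the repeat-dose tumors than A and B did. Leaving out such a tumor favors larger changes in advance. Without C edgeR called 100 genes, 96 higher and 4 lower after the repeat dose. In that fit Gzmb was at 3.25 (edgeR adjusted p = 0.0194), Il2ra at 3.48 (0.0289), Ifng at 3.10 (0.0188), Cd274 at 2.30 (0.0188), Nos2 at 2.28 (0.0356) and Prf1 at 2.24 (0.0194). Others were Il12rb1 at 2.16 (edgeR adjusted p = 0.0118), Socs1 at 2.14 (0.0288) and Irf1 at 1.59 (0.0329). Cxcl10 was at 1.49 (edgeR adjusted p = 0.0356) and Birc5 at -1.29 (0.0118). No list passed in fry with all samples, and 17 without replicate C. The smallest fry adjusted p with all samples was 0.111 for the 3 proliferation genes (relative median -1.01). The interferon-gamma response (relative median 0.5002) and cytotoxic effector lists (0.578, with 4 of 10 genes higher adjusted over the list alone) had a fry adjusted p of 0.199.

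Across the 729 genes, log2 changes after the second dose correlated with those after the first at a Pearson r of 0.736 (jackknife SE 0.185, Spearman 0.737). The 2 comparisons share no tumor. Deviations of single tumors from their group means also correlated across genes between groups. Late single-dose A had -0.710 with repeat-dose C and 0.642 with repeat-dose B, the lowest and highest of such pairs. An r of this size therefore does not by itself show that the second response repeats the first. Genes are not independent replicates, so no p is given, and with no gene past the threshold for the second dose an overlap of changed genes was not tested. Leaving out single tumors gave an r from 0.6002 to 0.793.

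**Figure D3:**
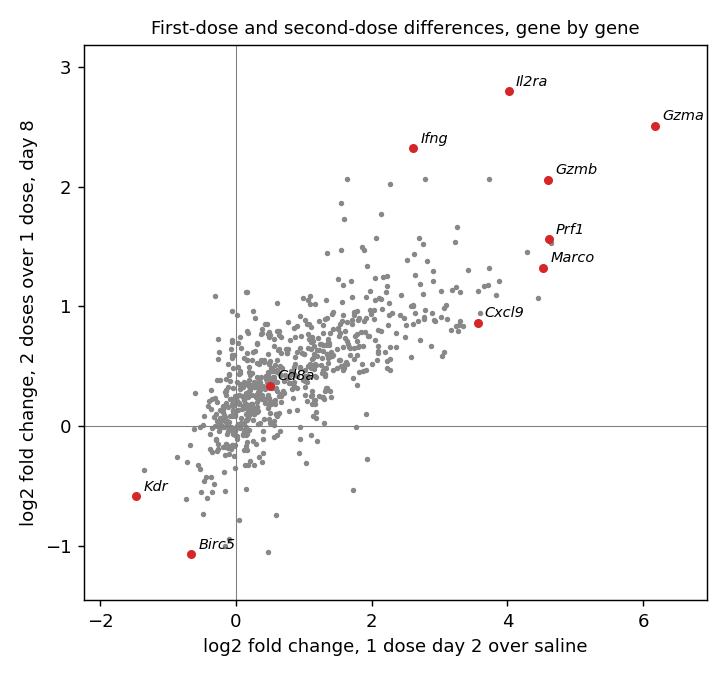
Log2 fold change of each of 729 genes in early single-dose tumors against saline (horizontal) and in repeat-dose against late single-dose tumors (vertical), with housekeeping scaling and 3 tumors per group. Each point is a gene, and the Pearson r is 0.736.

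The test of the difference between the second-dose and first-dose effects found no gene in edgeR, with 79 at an unadjusted p under 0.05. DESeq2 called 37 with its own factors and 18 with housekeeping factors, and limma called 0. Among the genes named next, Tcf7, Prf1, Gzma, Gbp5, Zbp1, Cxcl9, Il12rb1, Psmb8, H2-DMb1, Psmb10, Cxcl10, Irf1 and Cd274 passed in DESeq2 with either set of factors, and Gzmb with its own factors alone. The smallest edgeR adjusted p was 0.0780, for Tcf7 (-1.31 ± 0.22, relative -1.09), and 0.0341 under a stricter expression filter, where it alone passed. The mean scaled count of Tcf7 was 282 (SD 37.1, n = 3) in saline and 644 (SD 24.6, n = 3) in early single-dose tumors, and 430 (SD 20.02, n = 3) in late single-dose and 396 (SD 25.7, n = 3) in repeat-dose tumors. Prf1 had a difference of -3.05 ± 0.66 (relative -2.83, edgeR adjusted p = 0.305) and was the only gene past the threshold with TMM scaling (adjusted p = 0.00765). With total-count scaling Prf1 (adjusted p = 0.00709), Cxcl9, Gbp5, H2-DMb1 and Il12rb1 (0.0429 for each) passed, all negative. Gzma was at -3.66 ± 1.08 (edgeR adjusted p = 0.332). Gbp5 (-3.38 ± 0.90), Zbp1 (-2.74 ± 0.76), Cxcl9 (-2.70 ± 0.74), Il12rb1 (-2.67 ± 0.69), Psmb8 (-2.51 ± 0.69), H2-DMb1 (-2.48 ± 0.63) and Psmb10 (-2.37 ± 0.61) each had an edgeR adjusted p of 0.327. Further differences were Cxcl10 at -2.44 ± 0.73 (edgeR adjusted p = 0.332), Irf1 at -2.11 ± 0.64 (0.333), Cd274 at -2.54 ± 0.82 (0.339), Gzmb at -2.54 ± 0.94 (0.374) and Ncr1 at -1.68 ± 0.54 (0.339). Next came Il2ra at -1.22 ± 0.89 (edgeR adjusted p = 0.749), Nos2 at -1.53 ± 0.93 (0.671), Pdcd1 at -0.57 ± 0.49 (0.802), Ido1 at -0.40 ± 0.57 (0.920), Arg1 at -0.36 ± 1.12 (0.988) and Ifng at -0.29 ± 0.75 (0.988). Small differences, each with an edgeR adjusted p of 0.988, were Cd8a (-0.16 ± 0.52), Cd4 (-0.07 ± 0.61) and Il10 (-0.06 ± 0.61). So were S100a8 (-0.07 ± 0.91), Il12b (0.18 ± 0.88), Il2 (-0.22 ± 0.87) and Ms4a1 (0.03 ± 0.68). Without saline replicate A, 7 genes passed, among them Tcf7 (edgeR adjusted p = 0.0271), Psmb8 (0.0202), Psmb10 (0.0369) and H2-DMb1 (0.0393). Without late single-dose replicate C none passed, the median of all genes was -0.005, and several differences were smaller, with Gzmb at -1.35, Cd274 at -1.42, Il12rb1 at -1.72, Cxcl10 at -1.54, Il2ra at -0.55 and Nos2 at -0.44. In that fit 7 other differences turned positive: Ifng (0.49), S100a8 (0.49), Il2 (0.35), Cd4 (0.33), Arg1 (0.28), Cd8a (0.25) and Il10 (0.06). For Foxp3, below background in all day-8 tumors, no difference is given. No list passed in fry (smallest adjusted p = 0.463). Adjusted over the list alone in edgeR, 13 of 25 interferon-gamma response genes had a smaller second-dose effect (relative median -1.77). So had 10 of 16 class I (-1.62) and 3 of 10 class II genes (-1.70). The baseline of that effect, late single-dose tumors, was already above saline in these lists, so a weaker response is not shown.

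In late single-dose tumors, 8 days after the dose, 23 of 25 interferon-gamma response genes, 9 of 10 class II presentation genes and 12 of 22 T cell markers rose against the younger saline tumors. Cd8a had a mean scaled count of 207 (SD 90.7, n = 3) against 40.0 (SD 15.4, n = 3), and Marco 1582 (SD 449, n = 3) against 31.1 (SD 24.7, n = 3). In edgeR 285 genes rose, 1 fell and 443 did not pass. With TMM scaling 135 rose and 65 fell, and with total-count scaling 110 rose and 140 fell. With the positive controls alone 38 were higher and 1 lower. The count was 86 without saline replicate B, 108 without saline C and 107 without late single-dose C. A fit of these 6 tumors alone, with no spread shared from the other groups, called 0 genes. In that fit Marco was at 5.68, Cxcl9 at 3.46 and Cd8a at 2.37, each short of the threshold with an edgeR adjusted p of 0.0576.

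The largest rise was that of Marco (5.68 ± 1.01, relative 4.90, edgeR adjusted p = 0.00690). Next were Gbp5 (4.15 ± 0.71, relative 3.37, edgeR adjusted p = 0.00690), Nos2 (4.11 ± 0.74, relative 3.33, adjusted p = 0.00690) and the T cell chemokine Ccl5 (3.69 ± 0.60, relative 2.91, adjusted p = 0.00690). Gzma (3.69 ± 0.83, relative 2.91, edgeR adjusted p = 0.00937), Cd274 (3.66 ± 0.63, relative 2.88, adjusted p = 0.00690) and the class II chain H2-Aa (3.65 ± 0.74, relative 2.87, adjusted p = 0.00700) followed. Gzmk, a granule protease below background in all saline tumors, rose at least 12.0-fold (edgeR adjusted p = 0.00690) and has no place in that order. Only Itga4 fell (-0.93 ± 0.25, relative -1.72, edgeR adjusted p = 0.0179), with an adjusted p of 0.0590 without saline replicate B, 0.0632 without saline C and 0.0583 without late single-dose C. Gzma had an edgeR adjusted p of 0.0522 without saline replicate B.

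Of 29 lists 17 passed in fry and none in camera. Without saline replicate B or C 0 passed, without late single-dose A 10 and without late single-dose C 11. T cell markers rose in 12 of 22 cases (13 alone, relative median 0.489, fry adjusted p = 0.0200, adjusted p = 0.933 with an estimated correlation). Among them were Cd8a (2.37 ± 0.39, relative 1.59, edgeR adjusted p = 0.00690) and the T cell receptor chain Cd3g (2.44 ± 0.47, relative 1.66, adjusted p = 0.00700). Cytotoxic effectors rose in 9 of 10 (9 alone, relative median 1.68, fry adjusted p = 0.0157, adjusted p = 0.933 with an estimated correlation). Examples were Ctsw (2.44 ± 0.41, relative 1.66, edgeR adjusted p = 0.00690), Prf1 (2.73 ± 0.49, relative 1.94, adjusted p = 0.00690) and Gzmb (2.57 ± 0.69, relative 1.79, adjusted p = 0.0177). NK cell markers rose in 10 of 20 (11 alone, relative median 0.253, fry adjusted p = 0.0160, adjusted p = 0.933 with an estimated correlation). The rises included Klra2 (2.67 ± 0.49, relative 1.89, edgeR adjusted p = 0.00690), Klrc1 (1.86 ± 0.38, relative 1.08, adjusted p = 0.00700), Klrg1 (1.75 ± 0.36, relative 0.96, adjusted p = 0.00720) and Ncr1 (1.34 ± 0.38, relative 0.56, adjusted p = 0.0215). Th1 genes rose in 9 of 13 (9 alone, relative median 1.15, fry adjusted p = 0.0157, adjusted p = 0.933 with an estimated correlation). Members that rose included Cxcr6, a receptor of tissue T cells (3.37 ± 0.44, relative 2.59, edgeR adjusted p = 0.00498), Tnf (2.15 ± 0.47, relative 1.37, adjusted p = 0.00810) and Ifng (2.13 ± 0.55, relative 1.35, adjusted p = 0.0166).

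Interferon-gamma response genes rose in 23 of 25 cases (23 alone, relative median 1.92) and class I genes in 12 of 16 (12 alone, 1.59). Class II genes rose in 9 of 10 (9 alone, 2.52) and lymphocyte chemokines in 7 of 15 (10 alone, 1.40). Each of these 4 lists had a fry adjusted p = 0.0157 and an adjusted p = 0.933 with an estimated correlation. Examples were Cxcl9 (3.46 ± 0.56, relative 2.68, edgeR adjusted p = 0.00690) and Cxcl10 (2.78 ± 0.54, relative 2.00, adjusted p = 0.00700). Irf1 (2.52 ± 0.47, relative 1.74, edgeR adjusted p = 0.00700), H2-DMb1 (3.30 ± 0.48, relative 2.52, adjusted p = 0.00690) and Ciita (3.10 ± 0.60, relative 2.31, adjusted p = 0.00700) also rose. Interleukin receptor and signaling genes rose in 12 of 20 (13 alone, relative median 0.670) and inhibitory feedback genes in 10 of 13 (10 alone, 0.950). For each the fry adjusted p was 0.0160, with an adjusted p = 0.933 with an estimated correlation. Macrophage markers rose in 14 of 19 (15 alone, relative median 1.28, fry adjusted p = 0.0223, adjusted p = 0.933 with an estimated correlation). These included the growth factor receptor Csf1r (2.22 ± 0.49, relative 1.44, edgeR adjusted p = 0.00839) and the scavenger receptor Msr1 (2.59 ± 0.61, relative 1.81, adjusted p = 0.0119). Neutrophil markers rose in 5 of 15 (5 alone, fry adjusted p = 0.0490) although their median lay -0.123 from that of all genes and camera turned the direction (adjusted p = 0.951 with an estimated correlation). Among them were Fpr2 (3.44 ± 0.45, relative 2.66, edgeR adjusted p = 0.00498), S100a8 (3.09 ± 0.70, relative 2.31, adjusted p = 0.00969) and the Fc receptor Fcgr4 (2.47 ± 0.62, relative 1.69, adjusted p = 0.0152).

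Inflammatory cytokines rose in 12 of 21 cases (16 alone, relative median 0.845, fry adjusted p = 0.0331, adjusted p = 0.933 with an estimated correlation). An example was Il1rn, an inhibitor of interleukin-1 (2.68 ± 0.58, relative 1.90, edgeR adjusted p = 0.00810). Complement rose in 13 of 27 (15 alone, relative median 0.883, fry adjusted p = 0.0273), Toll-like receptors and adaptors in 9 of 23 (9 alone, 0.284, 0.0352), and checkpoint genes in 6 of 16 (6 alone, 0.115, 0.0487). Each had an adjusted p = 0.951 with an estimated correlation. Pdcd1 rose by 1.30 ± 0.35 (relative 0.52, edgeR adjusted p = 0.0183). Apoptosis genes rose in 8 of 18 (8 alone, fry adjusted p = 0.0238) with a median -0.414 from that of all genes. Camera (adjusted p = 0.951 with an estimated correlation) and TMM scaling (fry adjusted p = 0.412) turned the direction. The other 12 lists did not pass, among them type I interferon genes (16 of 28 rose, fry adjusted p = 0.0637). Arg1 rose by 2.84 ± 0.85 (relative 2.06, edgeR adjusted p = 0.0247).

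Without saline replicate B, saline C and late single-dose C in turn, the edgeR adjusted p was 0.0701, 0.0518 and 0.0721 for Ifng, 0.0739, 0.0667 and 0.0884 for Gzmb, and 0.0758, 0.0667 and 0.0774 for Pdcd1. In the same order it was 0.0926, 0.0788 and 0.104 for Arg1, and 0.0813, 0.0816 and 0.0704 for Ncr1. Ncr1 had 0.0660 without late single-dose A, and S100a8 0.0522 without saline B. Without saline B or late single-dose C the edgeR adjusted p of Msr1 was 0.0567 and 0.0512, and that of Fcgr4 0.0590 and 0.0583. Genes that did not pass were Il2ra (1.51 ± 0.65, edgeR adjusted p = 0.0905, 0.0321 without late single-dose B and 0.0378 with DESeq2 and housekeeping factors), Ido1 (0.74 ± 0.41, 0.176), Il10 (0.66 ± 0.43, 0.258), and Cd4 (0.55 ± 0.42, 0.340). Nor did Il2 (0.37 ± 0.60, edgeR adjusted p = 0.679), Ms4a1 (0.27 ± 0.48, 0.713), Il12b (0.11 ± 0.60, 0.921) and Foxp3 (0.651, below background in all late single-dose tumors) pass. With TMM scaling Pdcd1 (0.54, adjusted p = 0.145) and Ncr1 (0.59, 0.218) did not pass, nor with DESeq2's own factors (0.134 and 0.232). With total-count scaling they did not either (adjusted p = 0.348 and 0.363), nor did Klrg1 (0.0571) and Ifng (0.0687). With the positive controls alone Cd8a (adjusted p = 0.0538), Prf1 (0.0522), Klra2 (0.0535), Cd3g, Ctsw and Irf1 (0.0706 for each), Gzmb (0.133), Klrc1 (0.213), Klrg1 (0.260), Pdcd1 (0.450), Ncr1 (0.460) and Ifng (0.191) did not pass. Nor did Arg1 and Msr1 (adjusted p = 0.0900 for each), Tnf and Fcgr4 (0.132 for each) and Csf1r (0.134).

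Of the 3 treated groups, repeat-dose tumors had the highest count of genes that differed from saline. Marco had a mean scaled count of 3953 (SD 2677, n = 3) against 31.1 (SD 24.7, n = 3). Ifng had 513 (SD 219, n = 3) against 23.4 (SD 5.41, n = 3) and Cd274 8528 (SD 1068, n = 3) against 298 (SD 128, n = 3). Birc5 and Kdr fell, with Birc5 at 248 (SD 31.5, n = 3) against 781 (SD 22.6, n = 3) and Kdr at 125 (SD 8.01, n = 3) against 250 (SD 44.2, n = 3). In edgeR 433 genes rose, 14 fell and 282 did not pass. Scaling decided the split, with 234 higher and 169 lower by TMM, 159 and 250 by total count, and 115 and 157 by the positive controls alone. The negative probes, which have no target, were themselves 1.90 higher (log2) than in saline after housekeeping scaling. A rise up to about that size in a gene near background therefore cannot be told apart from scaled background. With background subtracted 379 genes were higher and 17 lower.

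Largest rises were those of Marco (7.002 ± 1.07, relative 5.81, edgeR adjusted p = 0.000770) and Gzma (6.20 ± 0.93, relative 5.00, adjusted p = 0.000770). Next were Nos2 (5.30 ± 0.78, relative 4.10, edgeR adjusted p = 0.000770) and Gbp5 (5.22 ± 0.74, relative 4.03, adjusted p = 0.000770). Another interferon-induced GTPase, Gbp2b (5.10 ± 0.99, relative 3.90, edgeR adjusted p = 0.00174), the surface enzyme Bst1 (4.92 ± 0.75, relative 3.72, adjusted p = 0.000770) and H2-T23 (4.85 ± 0.70, relative 3.65, adjusted p = 0.000770) followed. Gzmk, below background in saline, rose at least 28.8-fold (edgeR adjusted p = 0.000770) and is not placed in that order. The falls were led by Birc5 (-1.66 ± 0.24, relative -2.85, edgeR adjusted p = 0.000770), the growth regulator Myc (-1.50 ± 0.35, relative -2.70, adjusted p = 0.00375), and Itga4 (-1.30 ± 0.26, relative -2.50, adjusted p = 0.00191). The adhesion molecule Ncam1 (-1.20 ± 0.38, relative -2.40, edgeR adjusted p = 0.0188) and Hmgb1 (-1.14 ± 0.24, relative -2.34, adjusted p = 0.00212) came next. Mcam, an adhesion molecule of melanoma and vessel cells (-1.06 ± 0.33, relative -2.26, edgeR adjusted p = 0.0168), and Kdr (-0.996 ± 0.21, relative -2.19, adjusted p = 0.00245) fell too. So did the clotting protein Vwf (-0.99 ± 0.34, relative -2.19, edgeR adjusted p = 0.0265) and the cell-cycle kinase Cdk1 (-0.93 ± 0.31, relative -2.12, adjusted p = 0.0214). The edgeR adjusted p of Ncam1 was 0.0941 without saline replicate A and 0.0642 without repeat-dose B, and that of Mcam 0.0611 without saline A and 0.0513 and 0.0555 without repeat-dose B and C. For Vwf it was 0.0687 and 0.0546 without saline A and B and 0.0504, 0.0703 and 0.0698 without repeat-dose A, B and C. For Cdk1 it was 0.0505 and 0.0512 without saline B and C and 0.0700 and 0.0543 without repeat-dose B and C.

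Of 29 lists 26 passed in fry and none in camera. All 25 interferon-gamma response genes rose (25 alone, relative median 2.49), as did 9 of 10 cytotoxic effectors (9 alone, 2.52), and 13 of 16 class I genes (13 alone, 1.97). So did 9 of 10 class II genes (9 alone, 2.95), 11 of 13 Th1 genes (11 alone, 1.24) and 17 of 20 interleukin receptor and signaling genes (17 alone, 0.930). These lists shared a fry adjusted p = 0.000977 and an adjusted p = 0.942 with an estimated correlation. Examples were Ifng (4.45 ± 0.60, relative 3.26, edgeR adjusted p = 0.000770), Cxcl9 (4.33 ± 0.59, relative 3.13, adjusted p = 0.000770) and Cxcl10 (3.37 ± 0.56, relative 2.17, adjusted p = 0.000948). Further rises were those of Irf1 (3.43 ± 0.49, relative 2.24, edgeR adjusted p = 0.000770), the inflammatory protease Casp1 (4.09 ± 0.61, relative 2.89, adjusted p = 0.000770), and Gzmb (4.63 ± 0.76, relative 3.43, adjusted p = 0.000875). Prf1 (4.29 ± 0.52, relative 3.09, edgeR adjusted p = 0.000770) and H2-DMb1 (4.10 ± 0.50, relative 2.90, adjusted p = 0.000770) rose as well. So did Ciita (3.94 ± 0.62, relative 2.74, edgeR adjusted p = 0.000869), Cxcr6 (3.84 ± 0.45, relative 2.65, adjusted p = 0.000770) and Il2ra (4.31 ± 0.72, relative 3.11, adjusted p = 0.000948).

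T cell markers rose in 14 of 22 cases (14 alone, relative median 0.645, fry adjusted p = 0.00296, adjusted p = 0.942 with an estimated correlation). Cd8a rose by 2.71 ± 0.39 (relative 1.51, edgeR adjusted p = 0.000770). NK cell markers rose in 15 of 20 (15 alone, 0.394, fry adjusted p = 0.00132, adjusted p = 0.942 with an estimated correlation). The rises included Klrg1 (2.78 ± 0.37, relative 1.58, edgeR adjusted p = 0.000770) and Ncr1 (1.89 ± 0.39, relative 0.69, adjusted p = 0.00221). Ncr1 did not pass with TMM scaling (0.74, adjusted p = 0.0999), total-count scaling (0.26, 0.482), the positive controls alone (0.58, 0.394) or DESeq2's own factors (0.73, 0.102). Inhibitory feedback genes rose in 13 of 13 (13 alone, relative median 1.42) and lymphocyte chemokines in 12 of 15 (12 alone, 1.54), with a fry adjusted p = 0.00114 and an adjusted p = 0.942 with an estimated correlation for each. Cd274 (4.84 ± 0.67, relative 3.64, edgeR adjusted p = 0.000770) and Arg1 (4.61 ± 0.92, relative 3.42, adjusted p = 0.00200) were among the former. So were Il10, an anti-inflammatory cytokine (1.49 ± 0.44, relative 0.30, edgeR adjusted p = 0.0123), and Ido1, a tryptophan-degrading enzyme (1.34 ± 0.41, relative 0.15, adjusted p = 0.0151), both of which turned lower with total-count scaling (-0.20 and -0.29). With TMM scaling Il10 was at 0.30 (adjusted p = 0.502) and Ido1 at 0.16 (0.725), with DESeq2's own factors the adjusted p was 0.485 and 0.757, and with background subtracted 0.338 and 0.122. Without saline replicate B the edgeR adjusted p of Il10 and of Ido1 was 0.0505, and without repeat-dose A that of Il10 was 0.0647. Macrophage markers rose in 18 of 19 (18 alone, relative median 1.5003, fry adjusted p = 0.00389, adjusted p = 0.942 with an estimated correlation). Members that rose included Msr1 (3.76 ± 0.65, relative 2.56, edgeR adjusted p = 0.00107). Inflammatory cytokines rose in 18 of 21 (20 alone, relative median 1.24, fry adjusted p = 0.00319, adjusted p = 0.942 with an estimated correlation). These included Il1rn (3.51 ± 0.60, relative 2.31, edgeR adjusted p = 0.00107), the macrophage growth factor Csf1 (2.88 ± 0.55, relative 1.68, adjusted p = 0.00168) and Tnf (2.44 ± 0.47, relative 1.24, adjusted p = 0.00173). Tnf did not pass with total-count scaling (0.80, adjusted p = 0.0600) or the positive controls alone (0.90, 0.121).

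Type I interferon genes rose in 21 of 28 cases (22 alone, relative median 0.853, fry adjusted p = 0.00296, adjusted p = 0.942 with an estimated correlation). Complement rose in 15 of 27 (15 alone, 1.06, fry adjusted p = 0.00296, adjusted p = 0.945 with an estimated correlation). Checkpoint genes rose in 12 of 16 (13 alone, 0.221, fry adjusted p = 0.00389, adjusted p = 0.942 with an estimated correlation). Regulatory T cell genes rose in 7 of 11 (8 alone, 0.205, fry adjusted p = 0.00403, adjusted p = 0.945 with an estimated correlation). Foxp3 was not among them and lay below background in all repeat-dose tumors. Toll-like receptors and adaptors rose in 17 of 23 (17 alone, 0.0278, fry adjusted p = 0.00379, adjusted p = 0.945 with an estimated correlation). Pdcd1 rose by 1.98 ± 0.36 (relative 0.79, edgeR adjusted p = 0.00131), but did not pass with total-count scaling (0.42, adjusted p = 0.206) or the positive controls alone (0.52, 0.373). Neutrophil markers rose in 7 of 15 (7 alone, relative median 0.0817, fry adjusted p = 0.00763), and S100a8 by 4.56 ± 0.74 (relative 3.37, edgeR adjusted p = 0.000875). Alternatively activated macrophage genes rose in 8 of 14 (8 alone, 0.303, fry adjusted p = 0.0151) and dendritic cell markers in 9 of 17 (9 alone, 0.176, fry adjusted p = 0.0100). Camera turned the direction of these 3 lists (adjusted p = 0.945, 0.945 and 0.947 with an estimated correlation). In 5 further lists the members that passed mostly rose while the median lay below that of all genes, and camera and TMM scaling turned the direction. They were apoptosis (11 rose, 1 fell of 18, relative median -0.427, fry adjusted p = 0.00191, adjusted p = 0.945 with an estimated correlation), mast cells and eosinophils (3 of 8, -0.523, fry adjusted p = 0.0299, adjusted p = 0.942) and Th2 (6 of 11, -0.481, 0.0316, 0.942). The others were epithelium and skin (3 of 6, -0.0428, fry adjusted p = 0.0195, adjusted p = 0.942) and fibroblast and extracellular matrix (5 of 14, -0.682, 0.0362, 0.942).

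The 3 proliferation genes passed downward as a list (relative median -2.12, fry adjusted p = 0.000977, adjusted p = 0.146 with an estimated correlation). Birc5 and Cdk1 fell, and Ccnd3, a cyclin that promotes entry into division, rose by 0.52 ± 0.20 (edgeR adjusted p = 0.0365) but turned to -0.66 with TMM scaling. With the replicate letter as a block the adjusted p of Ccnd3 was 0.0568. The edgeR adjusted p of Ccnd3 was 0.129 and 0.0986 without saline replicates B and C, 0.0519, 0.0533 and 0.0506 without early single-dose A, B and C. It was 0.0539 without late single-dose A, and 0.0707, 0.0815 and 0.0697 without repeat-dose A, B and C. Of 17 endothelial genes 5 rose, 3 fell and 9 did not pass (relative median -0.911, fry adjusted p = 0.163), and with TMM scaling the list passed downward (fry adjusted p = 0.00332). Th17 genes (4 of 12 rose, fry adjusted p = 0.0956) and B cell markers (5 of 17, 0.147) did not pass. Genes that did not pass were Ms4a1 (0.42 ± 0.49, edgeR adjusted p = 0.489), Cd4 (0.37 ± 0.43, 0.501), Il2 (0.34 ± 0.62, 0.677), Foxp3 (0.872, below background in all repeat-dose tumors) and Il12b (-0.25 ± 0.62, 0.769). Il12b passed on the lower side with TMM scaling (-1.49, adjusted p = 0.0288), total-count scaling (-1.87, 0.0248), the positive controls alone (-1.79, 0.00978) and DESeq2's own factors (-1.48, 0.0122). Cd4 did so under the same settings (-0.85, -1.25, -1.14 and -0.86, adjusted p = 0.0179, 0.0117, 0.0478 and 0.00770), and Ms4a1 with the positive controls alone (-1.13, 0.0397).

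**Figure D4:**
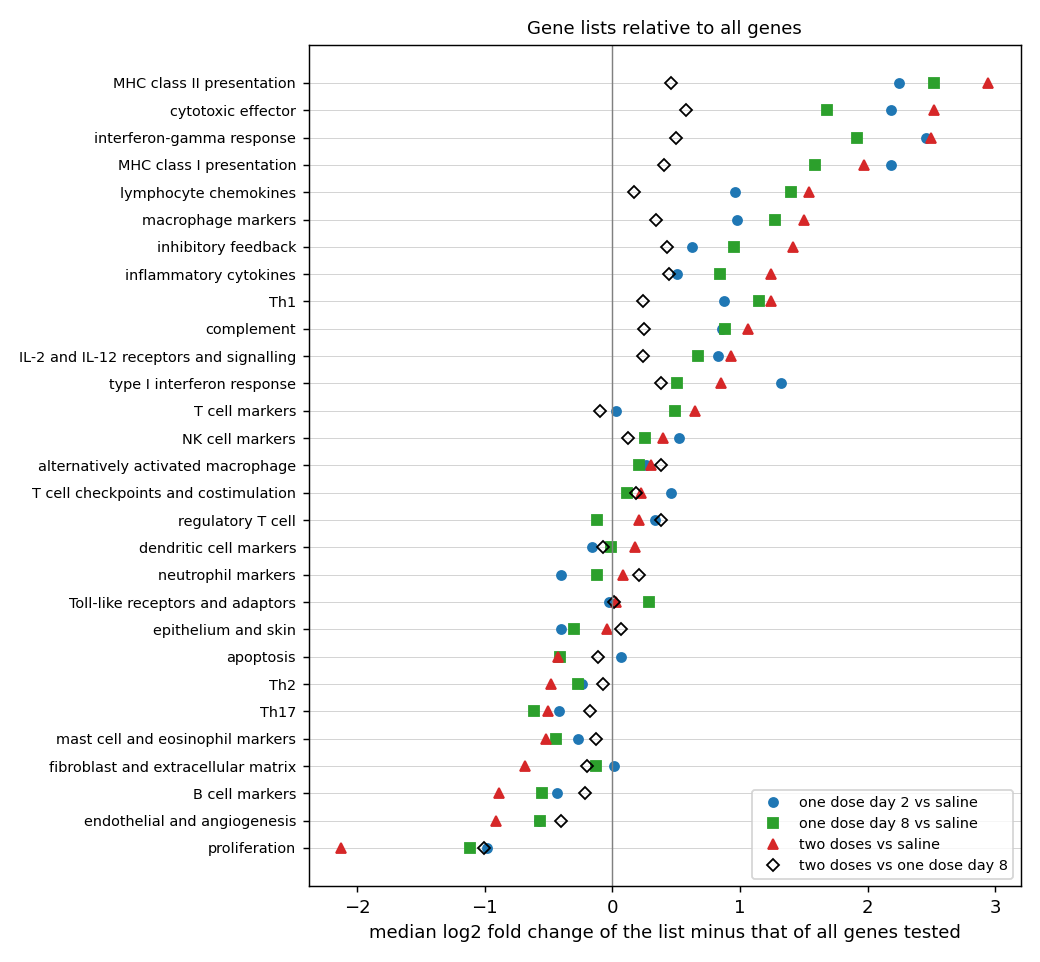
Median log2 fold change of the tested genes of each of 29 lists minus the median of all genes, for the comparisons of cytokine-treated tumors. Each point is a list in a comparison, for the interferon-gamma response 2.46 in early single-dose against saline tumors.

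Between day 2 and day 8 after a single dose no gene passed in edgeR (57 at an unadjusted p under 0.05). Cd8a had a mean scaled count of 207 (SD 90.7, n = 3) on day 8 and 56.5 (SD 12.6, n = 3) on day 2, a log2 difference of 1.87 ± 0.38 (relative 1.79, edgeR adjusted p = 0.136). Gzma had 956 (SD 568, n = 3) and 5339 (SD 1312, n = 3), a difference of -2.48 ± 0.78 (edgeR adjusted p = 0.276). DESeq2 called 57 genes with its own factors and 24 with housekeeping factors, limma 0, and edgeR with TMM scaling 14 (8 higher, 6 lower). With either set of factors the DESeq2 calls included Cd8a, Cxcr6, Cd3g, Fpr2, Kdr, Prf1, Il2ra, Gzmb and Gzma, and with housekeeping factors Tcf7. Those 14 included Cd8a (TMM adjusted p = 0.00784), Cxcr6 (1.68, 0.00784), Cd3g (1.47, 0.0378) and Fpr2 (1.1998, 0.0340) on the higher side and Prf1 (-2.17, 0.00241), Il2ra (-2.82, 0.00784), Gzmb (-2.42, 0.0129) and Gzma (-2.78, 0.0383) on the lower side. Values with housekeeping scaling were Cxcr6 1.94 ± 0.41 (edgeR adjusted p = 0.136), Cd3g 1.74 ± 0.46 (0.174), Prf1 -1.89 ± 0.46 (0.158), Gzmb -2.03 ± 0.67 (0.311) and Il2ra -2.52 ± 0.66 (0.174). Tcf7 was at -0.58 ± 0.16 (edgeR adjusted p = 0.174), Ncr1 at -0.89 ± 0.38 (0.590), Nos2 at 1.40 ± 0.66 (0.609) and S100a8 at 1.54 ± 0.66 (0.590). Kdr was at 1.06 ± 0.21 (edgeR adjusted p = 0.136). Without late single-dose replicate C, 5 genes passed, which were Gzmb (-3.22), Prf1 (-2.56), Kdr (1.17), Il12rb1 (-1.63) and Ifit2 (-1.86, an interferon-induced gene named only for its place in this fit), each with an edgeR adjusted p of 0.0465. Cxcl9 was at -0.10 ± 0.51 and Cd274 at -0.06 ± 0.57 (edgeR adjusted p = 0.998 for each). Further values were Ifng at -0.48 ± 0.52 (edgeR adjusted p = 0.905), Cxcl10 at -0.25 ± 0.51 (0.998), Irf1 at -0.49 ± 0.45 (0.903), Arg1 at 0.71 ± 0.80 (0.914) and Pdcd1 at 0.05 ± 0.35 (0.998). In the same comparison were Ido1 at -0.26 ± 0.40 (edgeR adjusted p = 0.994), Il10 at -0.24 ± 0.43 (0.998), Cd4 at 0.66 ± 0.43 (0.757) and Il12b at 0.65 ± 0.62 (0.903). Foxp3, below background in all late single-dose tumors, was at least 1.12-fold lower (edgeR adjusted p = 0.776). Il2 was at 0.18 ± 0.61 and Ms4a1 at 0.14 ± 0.48 (edgeR adjusted p = 0.998 for each). No list passed in fry, where the smallest adjusted p was 0.944.

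Repeat-dose and early single-dose tumors were each collected 2 days after their last dose, and differed in doses and age. Cd8a was at 2.21 ± 0.39 (relative 1.72) and Cxcr6 at 2.41 ± 0.42 (relative 1.92), each with an edgeR adjusted p of 0.0543, while Gzmb was at 0.03 ± 0.65 (0.985). The inflammatory cytokine Il1b had a mean scaled count of 601 (SD 405, n = 3) in repeat-dose and 72.4 (SD 23.7, n = 3) in early single-dose tumors. No gene passed in edgeR, with 176 at an unadjusted p under 0.05. DESeq2 called 57 and 79 genes with its own and with housekeeping factors, limma 2 (Cd8a and Cxcr6), and edgeR 19 with TMM scaling and 83 in a fit of these 6 tumors alone. With either set of factors the DESeq2 calls included Cd8a, Cxcr6, Il1b, S100a8, Il1rn, Cd3g, Fpr2, Tcf7, Birc5, Nos2, Gzmk, Ifng and Arg1. Further values were Il1b 3.06 ± 0.66, S100a8 3.02 ± 0.69, Il1rn 2.66 ± 0.58, Cd3g 2.03 ± 0.46, Fpr2 1.96 ± 0.42, Tcf7 -0.70 ± 0.16 and Birc5 -1.002 ± 0.23, each with an edgeR adjusted p of 0.0619. Nos2 was at 2.58 ± 0.68 and Gzmk at 2.49 ± 0.65 (edgeR adjusted p = 0.0816 for each), Ifng at 1.84 ± 0.53 (0.103) and Arg1 at 2.48 ± 0.84 (0.135). Prf1 was at -0.32 ± 0.45 (edgeR adjusted p = 0.657, and past the threshold with total-count scaling at -0.99, 0.0479, and with DESeq2's own factors at -0.87, 0.0389) and Il2ra at 0.28 ± 0.62 (0.788). Interferon-induced genes were Cxcl9 at 0.77 ± 0.51 (edgeR adjusted p = 0.356), Cxcl10 at 0.34 ± 0.51 (0.693), Irf1 at 0.42 ± 0.45 (0.557) and Cd274 at 1.12 ± 0.58 (0.257). Fixed genes beside these were Pdcd1 at 0.73 ± 0.35 (edgeR adjusted p = 0.228), Il10 at 0.60 ± 0.43 (0.379), Ido1 at 0.34 ± 0.40 (0.596), Ncr1 at -0.34 ± 0.37 (0.569) and Cd4 at 0.48 ± 0.43 (0.476). Last were Il12b at 0.29 ± 0.63 (edgeR adjusted p = 0.788), Il2 at 0.15 ± 0.63 (0.885) and Ms4a1 at 0.30 ± 0.49 (0.714). Foxp3 (edgeR adjusted p = 0.700) was below background in all repeat-dose tumors and has no fold.

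The count in that comparison was 49 without late single-dose replicate C, 27 without late single-dose B, 14 without repeat-dose B, 8 without saline C and 6 without saline A. Cd8a passed in each of these fits (edgeR adjusted p = 0.0274, 0.0331, 0.0353, 0.0309 and 0.0358), as did Cxcr6 (0.0274, 0.0331, 0.0353, 0.0301 and 0.0222) and Il1rn (0.0342, 0.0385, 0.0353, 0.0301 and 0.0485). Without late single-dose C, B and repeat-dose B the edgeR adjusted p was 0.0342, 0.0385 and 0.00962 for Il1b and 0.0342, 0.0464 and 0.00962 for S100a8. Without late single-dose C and B it was 0.0314 and 0.0331 for Cd3g and Fpr2, 0.0314 and 0.0385 for Tcf7 and Nos2, 0.0274 and 0.0385 for Birc5, and 0.0438 and 0.0385 for Gzmk, and without late single-dose C 0.0342 for Ifng. No list passed in fry, where the smallest adjusted p was 0.222. A gene past the threshold against saline in only 1 of these groups is not shown to differ between them.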

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

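The tests of late single-dose replicate C and of the housekeeping probes in this part were chosen after the results were seen, while the splits of the samples were planned. The housekeeping probes served only for scaling and enter no comparison of the report, and 10 of their values stood out because the ratio of a probe to the other housekeeping probes was higher than in saline tumors (limma, Benjamini-Hochberg over 60 tests, adjusted p under 0.05). In early single-dose tumors these were G6pdx, an enzyme of the pentose phosphate pathway (0.61, log2), Alas1, an enzyme of heme synthesis (0.31), Rpl19 (0.26) and Tubb5 (0.23). In late single-dose tumors they were Alas1 (0.69) and G6pdx (0.66), and in repeat-dose tumors G6pdx (1.19), Alas1 (0.85), Rpl19 (0.42) and Polr2a (0.36). Lower ratios past the test were found for 3, 3 and 7 of the 20 probes in the same order.

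Housekeeping counts were lower after treatment while the total count of the other genes was not. Less RNA in the assay would lower both. The log2 ratio of total to housekeeping mean was 1.63 higher in repeat-dose than in saline tumors, beyond 2 SD of saline (0.218). This argues against less RNA as the whole source, but less RNA with induced genes stays open. A fixed background lifted by the scaling as the negative probes were (by 1.90) would add at most 0.35 to a gene at 10 times the background limit, but the median of 335 genes at or above that level in saline was 1.01 higher (0.80 to 1.14 by tumor), which argues against it as the whole source. A few genes taking most of the counts would spare the ratio once they are removed, but without the 20 genes with most counts it was still 1.49 higher (SD of saline 0.207). Immune cells in place of tumor cells may give such a pattern, a hypothesis untested here because melanocyte genes were too few on the panel.

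Late single-dose replicate C lay nearer to the repeat-dose tumors (0.323 from their mean) than replicates A (0.599) and B (0.861) did, and decided the count of genes for the second dose (0 with it, 100 without), though within its own group B lay no nearer to the mean of the others (0.610) than C did (0.592). A swap with a repeat-dose tumor would place 1 of those tumors nearer to replicates A and B than to its own group, and 0 were, but repeat-dose C was nearly as far from its own group (0.699) as from A and B (0.743), a gap within the SD of such distances (0.109), so that a swap stays open. A single wrong label, a repeat-dose tumor named as single-dose, stays open too, since replicate C was nearer to the mean of the repeat-dose tumors than to that of A and B (ratio of distances 0.545 over 562 genes). Tumor by tumor the ratio was 0.777 (0.504 against 0.648), while A and B were 0.568 apart and repeat-dose tumors 0.616 to 0.742 from one another on average. Lower depth does not account for it, since the total of C was 1.62 times that of B, and a true difference between mice may equally be the source and was not tested.

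With 3 against 3 tumors there are 10 ways to split 6 samples, too few to weigh chance. The real split called 227 genes for early single-dose against saline (1 of 10 splits with as many, highest other 0), 286 for late single-dose against saline (1 of 10, highest other 0) and 447 for repeat-dose against saline (1 of 10, highest other 0). It called 0 for repeat-dose against late single-dose tumors (10 of 10, highest other 1) and 0 for late against early single-dose tumors (10 of 10, highest other 0). For repeat-dose against early single-dose tumors it called 0, which any split equals (10 of 10), and another split called 69. Over all 12 tumors the joint test called 356 genes, more than any other of 100 splits (1 of 100, highest other 258), so that random assignment does not account for it at that number of splits. The difference of the effects called 0, which any split equals (100 of 100), and another split called 242. Splits of all 12 tumors mix treated and saline tumors, whose own differences enter such a count, and no further structure was tested.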

How the results depend on the processing

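Counts of changed genes in edgeR under other settings, for each of which the cause was not tested unless stated, were as follows. Positive-control scaling gave 87 genes for early single-dose against saline, 39 for late single-dose against saline, 272 for repeat-dose against saline and 108 in the joint test. A fit of only the groups compared, which has fewer samples to estimate the spread, gave 0 for late single-dose against saline and 83 for repeat-dose against early single-dose tumors. For late against early single-dose tumors TMM gave 14, total count 16, and DESeq2 57 (own factors) and 24 (housekeeping factors). For repeat-dose against early single-dose tumors TMM gave 19, total count 28, the stricter filter 18, DESeq2 57 and 79, and limma 2. For repeat-dose against late single-dose tumors DESeq2 gave 10 and 3. For the difference of the effects TMM gave 1, total count 5, the stricter filter 1, and DESeq2 37 and 18. Leaving out single samples gave 89 to 268 genes for early single-dose, 86 to 361 for late single-dose and 377 to 469 for repeat-dose against saline, 0 to 100 for repeat-dose against late single-dose, 0 to 5 for late against early single-dose, 0 to 49 for repeat-dose against early single-dose, 0 to 7 for the difference of the effects and 173 to 398 in the joint test. The correlation of the effects ranged from 0.6002 to 0.793, and was 0.759 with TMM and 0.726 with no filter. With single samples left out, lists past the threshold in fry ranged from 9 to 20 for early single-dose, 0 to 23 for late single-dose and 21 to 27 for repeat-dose against saline, 0 to 17 for repeat-dose against late single-dose tumors and 0 to 0 elsewhere. With camera, 0 lists passed against saline in each group, and with TMM 16 passed for repeat-dose against saline, 2 for late against early single-dose and 3 for the difference of the effects. Directions turned with camera for neutrophil and apoptosis lists in late single-dose against saline (adjusted p = 0.951 for each), and in repeat-dose against saline for Th2, mast cell and eosinophil, fibroblast, and epithelium lists (0.942), dendritic cells (0.947), and alternatively activated macrophage, neutrophil and apoptosis lists (0.945). With TMM (fry adjusted p) they turned for apoptosis (0.412) and endothelial genes (0.0442) in late single-dose against saline, and in repeat-dose against saline for Th2 (0.513), mast cells and eosinophils (0.352), apoptosis (0.211), endothelial genes (0.00332), fibroblasts (0.106) and epithelium (0.212). In repeat-dose against saline single genes turned, in log2, for Ccnd3 (TMM -0.66, total -1.09, positive controls -0.94, DESeq2 own factors -0.67), Cd4 (-0.85, -1.25, -1.14 and -0.86 in that order), Il10 (total -0.20), Ido1 (total -0.29, positive controls -0.15) and Ms4a1 (positive controls -1.13). Of 254 results of single genes chosen by the rule and reported, 118 were past the threshold. For these, 1340 of 1416 values with a sample left out kept their call and 76 lost it, and under other settings 1309 of 1408 kept it, 92 lost it and 7 reversed. For the rest 58 of 1632 values came to pass with a sample left out, and under other settings 174 of 1577 came to pass and 5 reversed. Of 58 list results past the threshold, 600 of 696 values with a sample left out and 97 of 174 under other settings kept their call, 96 and 61 lost it, and 16 reversed. For list results not past it, 43 of 1740 came to pass with a sample left out, and 9 of 435 came to pass and 2 reversed under other settings. With background subtracted 4 fold changes of Foxp3 could not be estimated, since a group had no count left. The replicate letter as a block gave 226, 0, 275, 441, 0, 0, 0 and 340 genes in the order of the design, with no count moved by over 1.5 times, and tumors with the same letter had a mean correlation of 0.0369 (from -0.650 to 0.596) against -0.0142 for others, a gap small beside that range. Repeat-dose replicate C had the lowest depth, at 392596 counts, so genes near background are least sure there.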

Other observations

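The effector score in this part was chosen after the results were seen. Group means of scaled counts of Il1b were 89.1 (SD 40.5, n = 3) in saline, 72.4 (SD 23.7, n = 3) in early single-dose, 282 (SD 116, n = 3) in late single-dose and 601 (SD 405, n = 3) in repeat-dose tumors. Arg1 had 287 (SD 260, n = 3), 1255 (SD 517, n = 3), 2051 (SD 1439, n = 3) and 7014 (SD 5426, n = 3) in the same order, and S100a8 73.8 (SD 18.2, n = 3), 215 (SD 91.7, n = 3), 627 (SD 350, n = 3) and 1744 (SD 1219, n = 3). Foxp3 was below background in all late single-dose and repeat-dose tumors. An effector score was computed per tumor as the mean log2(count + 1) of 10 cytotoxic effector genes minus that of 41 T cell and NK cell marker genes, without a test. It was -0.56 (SD 0.24, n = 3) in saline, 1.52 (SD 0.25, n = 3) in early single-dose, 0.66 (SD 0.38, n = 3) in late single-dose and 1.51 (SD 0.37, n = 3) in repeat-dose tumors.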
